A study of Malassezia restricta with 18 samples.

How the data were processed

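A set of 18 RNA sequencing libraries from cultures of the yeast Malassezia restricta, strain MYA-4611, was analysed. Per the labels, cells were grown in modified Dixon medium, a rich medium that supplies the lipids Malassezia yeasts need, for 24 h at 33 °C with shaking. The labels place 3 libraries in each of 6 groups, namely an untreated control at 0 h and cultures with sodium propionate, the salt of a short-chain fatty acid, at 0.5, 3, 6, 12 and 24 h. Each library carries a biological replicate number in the labels. Groups and replicate numbers were taken from those labels. The propionate dose is not given in the sources used here. The only untreated group is at 0 h, so an effect of propionate cannot be separated from an effect of time in culture in any comparison against the control.

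The deposited count table holds whole-number read counts for 4096 locus tags in 18 columns, with a length for each tag. All 4096 lengths are multiples of 3, so they are coding lengths; they run from 210 to 14529 bases with a median of 1266. The deposited FPKM table holds, for the same tags and libraries, the count per kilobase of coding length per 1000000 counts summed over the 4096 tags. Recomputing that formula on all 73728 values gave a largest relative difference of 5.07e-15, so the FPKM values add no measurement and were not tested. Columns were matched to libraries by the time and replicate number in their names. The 3 columns whose names begin with 5 were taken as the 0.5 h libraries, because no other time in the labels contains that digit, and 0 columns were left unmatched. Per the submitters' processing notes, the tools used upstream include Trimmomatic 0.38, SAMtools 1.13 and DESeq2 1.30.1. The aligner, the read counter, the genome build and any strand setting are not given in the sources used here, so reads shared between near-identical or overlapping genes could have been split or dropped in ways that were not checked.

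The files give no gene names or products. A table of genes from another strain of the species was searched for the locus tags, and 0 of 4096 matched, so genes are given by locus tag alone and without coordinates. For the same reason, 26 gene lists chosen in advance could not be matched to any tag, and 0 of them were tested. The rule for the genes named in the text was the following. In each comparison, genes past the threshold were ranked by the size of their log2 fold change, if all 3 libraries of one group lay on one side of all 3 libraries of the other and the mean was at least 5 counts-per-million (CPM) in either group. The 2 with the largest rise and the 2 with the largest fall were named. Genes named outside this rule are marked as chosen after their values were seen.

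Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter at its minimum count of 10, which left 4088 genes. Libraries were scaled by the trimmed mean of M values (TMM), a method that assumes that most genes do not change between libraries. A quasi-likelihood model with 1 mean per group was fitted to all 18 libraries, so that the groups shared 1 estimate of spread, and each treated group was contrasted with the control. The 24 h group was also contrasted with the 0.5 h group, and a joint test over the 5 contrasts asked whether a gene departed from control at any time. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Levels are CPM on TMM-scaled library sizes, and standard errors of log2 fold changes were derived from the F statistic. The common biological coefficient of variation was 0.26. Single values of groups of 3 were compared by exact two-sided permutation tests, whose smallest possible p in this design is 0.1.

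The position of a library between control and 24 h was computed from log2 CPM with a prior count of 2. It is the projection of the library on the line from the control mean to the 24 h mean, with the library left out of the mean of its own group, and it is 0 at the control mean and 1 at the 24 h mean. Correlations between comparisons that share the control libraries were set against 50 simulations in which no group changed.

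The test was checked on simulated counts for 4087 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For the 0.5 h comparison it recovered 61% of the 2-fold and 99% of the 4-fold changes, and 3.03% of its calls were false. For the 24 h comparison it recovered 53% and 94%, and 8.13% of its calls were false, above the nominal 5%. The simulated groups had the same spread and few changed genes, which is what the model and TMM assume. In the data 62.3% of genes were called at 24 h, so these rates need not hold there. Total counts ran from 14960115 to 17118765 per library. No pair of libraries agreed within sampling noise. The lowest chi-square per degree of freedom over all pairs was 27, between replicates 1 and 2 at 24 h. No library was therefore a repeat count of another, and each was kept. The check cannot show that libraries came from separate cultures, which rests on the replicate numbers in the labels.

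The groups, tests, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were DESeq2 size factors within edgeR, scaling by total count only, no low-count filter, a stricter filter, the replicate number as a block, DESeq2 1.42.0, voom in limma 3.58.1, a fit of only the groups compared, and each library left out in turn. A fit without replicate 2 at 6 h and replicate 3 at 12 h, and a fit on libraries thinned to 1 total count, were added after the data had been seen.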

Results

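RNA sequencing was used to follow gene expression in Malassezia restricta, a lipid-dependent yeast of human skin, over 24 h with sodium propionate. The title of the series gives its subject as the way in which propionate inhibits growth of this yeast. An untreated control at 0 h and treated cultures at 0.5, 3, 6, 12 and 24 h were each represented by 3 biological replicates per the labels. Total counts were 16063606 to 17118765 in the control libraries, 15309822 to 17076468 at 0.5 h, 15679276 to 16736499 at 3 h, 15145178 to 15988393 at 6 h, 15234342 to 15657527 at 12 h and 14960115 to 15188341 at 24 h. Of 4096 locus tags, 4088 had enough counts to be tested. The tags carry no gene names in the data used here, so genes are given by tag.

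The counts became concentrated in few genes as the time course went on. In the control, the 10 most abundant genes of each library held 9.50% ± 0.89 of its counts (SD, n = 3), against 8.44% ± 0.33 at 0.5 h, 9.94% ± 0.58 at 3 h, 12.4% ± 3.37 at 6 h, 21.7% ± 7.26 at 12 h and 32.1% ± 4.48 at 24 h. The number of genes that together held 50% of the counts rose from 253 ± 19.5 in the control to 326 ± 2.65 at 0.5 h and was 32.0 ± 10.6 at 24 h. DNF11_2791 was the most abundant gene in all 3 control and all 3 libraries at 0.5 h, and DNF11_3732 in all 3 libraries at 3, 12 and 24 h. Both genes were singled out after their values were seen. DNF11_3732 alone held 10.3% to 13.3% of the counts in the 24 h libraries. For the share of the 10 most abundant genes, the exact permutation test against the control gave p = 0.1 at 0.5, 12 and 24 h, the smallest that 3 libraries against 3 allow, p = 0.5 at 3 h and p = 0.2 at 6 h. The median count of a gene was 1439 ± 22.5 in the control and 296 ± 77.8 at 24 h, so genes of low abundance were measured with fewer counts at 24 h.

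**Figure D1:**
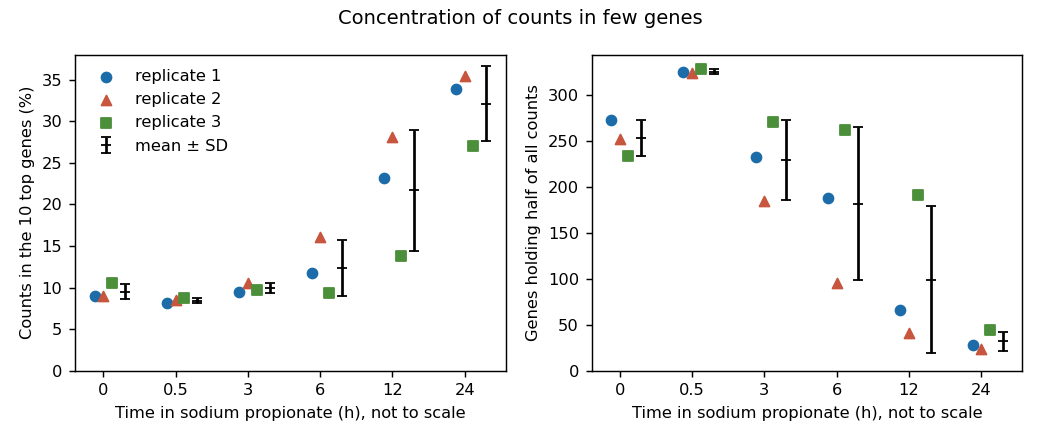
Share of each library's counts in its 10 most abundant genes (left, in percent) and number of genes that hold 50% of the counts (right) by time in sodium propionate in hours, with a point per library, its shape and colour giving the replicate number, and black bars giving mean ± SD of 3 libraries. The share was at most 10.6% in the control, 0.5 h and 3 h libraries and lay between 27% and 35.4% at 24 h.

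This shift makes the scale of the comparison matter. On the TMM scale used below, the median log2 fold change of all tested genes against the control was 0.02 at 0.5 h, -0.04 at 3 h, -0.01 at 6 h, -0.02 at 12 h and -0.10 at 24 h. When libraries were scaled by their total count alone, the same medians were 0.17, -0.15, -0.32, -0.84 and -2.06. A rise or fall on the TMM scale is therefore a change relative to the typical gene, and the split under the other scale is given beside each main split that it moved by more than 10 percentage points.

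At 0.5 h, 291 genes were higher and 202 lower than in the control, and 149 of the former and 122 of the latter changed at least 2-fold. The largest rises by the rule for named genes were in DNF11_0394, from 2.65 ± 0.23 to 16.4 ± 3.2 CPM (SD, n = 3), and DNF11_3966, from 32.7 ± 12.5 to 195 ± 52.6 CPM. Their log2 fold changes were 2.63 ± 0.34 (SE) and 2.57 ± 0.25, with edgeR adjusted p-values of 6.12e-05 and 3.39e-06. The largest falls were in DNF11_1265, from 4236 ± 727 to 292.0 ± 33.1 CPM, and DNF11_3555, from 243 ± 55.5 to 17.3 ± 7.0 CPM. These were 14.5-fold and 14-fold lower, with adjusted p-values of 0.000525 and 6.82e-07. The count of 493 called genes was the least stable of the time course. It was 205 with scaling by total count, 748 with DESeq2, 1060 when only the 6 libraries of these groups were fitted and 862 without replicate 2 at 6 h and replicate 3 at 12 h, and it was 315 without control replicate 1, 277 without control replicate 3, 308 without replicate 1 at 0.5 h and 299 without replicate 3 at 0.5 h.

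At 3 h, 613 genes were higher and 634 lower than in the control. DNF11_3977 rose 33.3-fold, from 149 ± 56.8 to 4952 ± 3979 CPM (SD, n = 3), with a log2 fold change of 5.06 ± 1.08 (SE) and an adjusted p of 0.00172 in edgeR. DNF11_2687 rose 12.6-fold, from 128 ± 22.1 to 1606 ± 1192 CPM (adjusted p = 0.00107). DNF11_1535 was 18.1-fold lower, at 206 ± 30.8 CPM against 3724 ± 940 in the control (adjusted p = 4.75e-07). DNF11_3555, among the largest falls at 0.5 h, stood at 26.3 ± 1.23 CPM and was 9.22-fold lower than the control (adjusted p = 1.01e-06). The 2 genes that rose were spread widely between replicates, with SDs close to their means, while the 2 that fell were not. Without replicate 2 at 3 h, the log2 fold change was 4.30 for DNF11_3977 and, against 3.65 with it, 2.91 for DNF11_2687. The count of 1247 called genes was 629 with scaling by total count and 2017 in a fit of only the 6 libraries compared.

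At 6 h, 652 genes were higher and 688 lower than in the control. DNF11_3977 reached 19870 ± 18230 CPM (SD, n = 3), a log2 fold change of 7.06 ± 1.19 (SE, adjusted p = 0.000212 in edgeR). DNF11_3943, at 27.8 ± 6.07 CPM in the control, reached 876 ± 774 CPM, 31.5-fold higher (adjusted p = 9.85e-05). DNF11_1535 was 11.2-fold lower at 333 ± 35.8 CPM (adjusted p = 1.45e-06), and DNF11_0296 fell from 90.1 ± 29.3 to 8.97 ± 2.14 CPM, 9.97-fold lower (adjusted p = 9.37e-07). Replicate 2 at 6 h was the highest 6 h library for both genes that rose, and both rises remained without it. The log2 fold change was then 6.05 for DNF11_3977 and 3.99 for DNF11_3943, against 7.06 and 4.98 with it. By total count the 2 values were 6.44 and 4.38. With scaling by total count 758 genes were called, 287 higher and 471 lower, so that 37.9% of the calls were higher against 48.7% on the TMM scale.

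At 12 h, 940 genes were higher and 870 lower than in the control. DNF11_3977 was 243-fold higher, at 36150 ± 32290 CPM (SD, n = 3), with a log2 fold change of 7.93 ± 1.23 (SE, adjusted p = 8.13e-05 in edgeR). DNF11_3943 was 55.1-fold higher, at 1532 ± 1213 CPM (log2 fold change 5.79, adjusted p = 2.87e-05). Without replicate 2 at 12 h the log2 fold changes of these 2 genes were 7.02 and 5.03, and by total count they were 6.54 and 4.47. DNF11_0296 was 12.7-fold lower, at 6.90 ± 2.93 CPM (adjusted p = 5.13e-07). DNF11_3736 was 11.3-fold lower, at 53.3 ± 10.4 CPM against 601.3 ± 16.1 in the control (adjusted p = 4.64e-08). By total count the log2 fold changes of DNF11_0296 and DNF11_3736 were -4.35 and -4.24, against -3.66 and -3.49 on the TMM scale. With scaling by total count, 269 genes were higher and 1613 lower, so that 14.3% of the calls were higher against 51.9% on the TMM scale. Replicate 3 at 12 h lay apart from the other 12 h libraries, and the count of 1810 was 2311 without it and 1161 in a fit of only the 6 libraries compared.

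At 24 h, 1215 genes were higher and 1333 lower than in the control, 62.3% of the genes tested. The change was at least 2-fold in 906 of the genes that rose and 800 of those that fell. DNF11_3977 rose from 149 ± 56.8 to 74700 ± 43150 CPM (SD, n = 3), a log2 fold change of 8.97 ± 1.29 (SE, adjusted p = 1.7e-05 in edgeR). Its level in replicate 3 at 24 h was 25985 CPM, against 90031 in replicate 1 and 108090 in replicate 2. DNF11_3943 rose 124-fold to 3456 ± 871 CPM, a log2 fold change of 6.96 ± 0.85 (adjusted p = 3.26e-06). DNF11_3109 fell from 31.1 ± 6.69 to 1.65 ± 0.78 CPM, 18.7-fold lower (adjusted p = 1.38e-06). Its 24 h level rests on 4, 10 and 14 counts in replicates 1, 2 and 3, so the size of the fall is uncertain. DNF11_0296 fell from 90.1 ± 29.3 to 5.37 ± 0.27 CPM, 16.7-fold lower (adjusted p = 1.5e-07). With scaling by total count, 229 genes were higher and 3327 lower, so that 6.44% of the calls were higher against 47.7% on the TMM scale. The genes called in the same direction under both scales numbered 229 higher and 1333 lower, and DNF11_3977 and DNF11_3943 were among the former with log2 fold changes of 6.87 and 4.94 by total count. By total count DNF11_3109 and DNF11_0296 changed by -6.19 and -6.04, against -4.23 and -4.06 on the TMM scale.

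**Figure D2:**
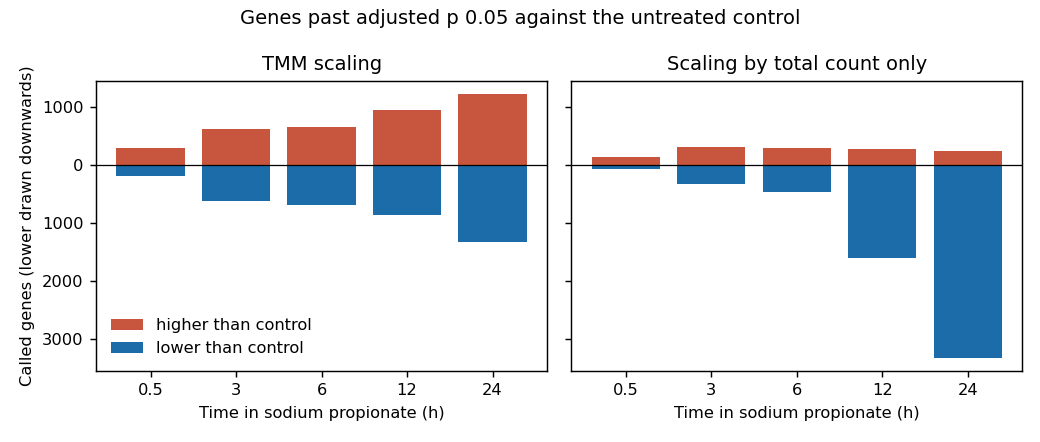
Genes with an adjusted p under 0.05 against the untreated control (vertical axis, number of genes, higher drawn upwards and lower drawn downwards) by time in sodium propionate in hours, with TMM scaling on the left and scaling by total count on the right. At 24 h the split was 1215 higher and 1333 lower with TMM and 229 higher and 3327 lower by total count.

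Over the whole time course, 2888 of 4088 genes (70.7%) departed from control in the joint edgeR test over the 5 times, and 1094 were called at none of them. At all 5 times 154 genes were higher and 86 lower than in the control. From 3 h onwards, 399 genes were higher and 436 lower at each of the 4 times, and in 146 and 142 of these the estimated change was larger at each later time. These counts are on the TMM scale. By total count, 229 genes were higher at 24 h, so no more than that could be higher at each of these times. The 1215 genes that were higher at 24 h had median log2 fold changes of 0.10 at 0.5 h, 0.46 at 3 h, 0.69 at 6 h, 1.07 at 12 h and 1.53 at 24 h. For the 1333 genes that were lower at 24 h the medians were -0.06, -0.45, -0.56, -0.72 and -1.12. Both sets were chosen at 24 h, so their 24 h medians are the largest in part by selection.

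The response at 0.5 h differed from that at 24 h. In the direct comparison, 1187 genes were higher and 1357 lower at 24 h than at 0.5 h. DNF11_2824 rose from 81.4 ± 5.63 CPM at 0.5 h to 30350 ± 6447 CPM at 24 h (SD, n = 3), a log2 fold change of 8.54 ± 0.78 (SE, adjusted p = 2.91e-07 in edgeR). DNF11_2693 rose from 191 ± 91.0 to 42650 ± 14140 CPM, 223-fold higher (adjusted p = 1.49e-06). DNF11_3109 was 12.0-fold lower at 24 h than at 0.5 h (adjusted p = 7.48e-06). DNF11_3540 fell from 13.3 ± 1.64 to 1.38 ± 0.47 CPM, 9.97-fold lower (adjusted p = 7.48e-06). The 24 h level of DNF11_3540 rests on 8, 8 and 6 counts in replicates 1, 2 and 3. That of DNF11_3109 is also near the floor, so the sizes of both falls are uncertain. DNF11_2824 was 11.8-fold below the control at 0.5 h (adjusted p = 0.000917) and 31.7-fold above it at 24 h (adjusted p = 8.63e-06), where its log2 fold change was 4.99 on the TMM scale and 2.97 by total count. For 24 h against 0.5 h, the log2 fold changes by total count were 6.38 for DNF11_2824, 5.62 for DNF11_2693, -5.69 for DNF11_3109 and -5.45 for DNF11_3540, against 8.54, 7.80, -3.59 and -3.32 on the TMM scale. With scaling by total count, 195 genes were higher and 3455 lower at 24 h than at 0.5 h, so that 5.34% of the calls were higher against 46.7% on the TMM scale.

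Genes called at 0.5 h followed different courses. Of the 291 genes higher at 0.5 h, 173 were also higher at 24 h, 35 were lower and 83 were not called. Of the 202 genes lower at 0.5 h, 99 were also lower at 24 h, 53 were higher and 50 were not called. These counts are on the TMM scale. By total count 130 genes were higher at 0.5 h, so no more than 130 could be higher at both times. In the direct contrast of 24 h with 0.5 h, 119 of the 291 were lower and 89 higher at 24 h, and 103 of the 202 were higher and 31 lower, where 1187 of all 4088 genes were higher and 1357 lower. Both sets were chosen on the same 0.5 h libraries, so a return towards the control at 24 h is in part favoured by selection. DNF11_1265, the largest fall at 0.5 h, stood at 35730 ± 10170 CPM at 24 h (SD, n = 3), 8.44-fold above the control (adjusted p = 0.000362 in edgeR); its log2 fold change by total count was 1.04 (adjusted p = 0.00296). DNF11_3966 declined from its level at 0.5 h to 68.1 ± 4.75 CPM at 24 h, 2.86-fold lower than at 0.5 h (log2 fold change -1.51, adjusted p = 6.03e-05), and by total count the log2 fold change was -3.61. It was still 2.08-fold above the control on the TMM scale (adjusted p = 0.00133), but by total count its log2 fold change was -0.91 (adjusted p = 0.0696). DNF11_3555 was lower than the control at each of the 5 times, by 8.10-fold to 14-fold on the TMM scale; by total count its log2 fold change was -3.89 at 12 h and -5.08 at 24 h, against -3.25 and -3.10 with TMM.

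**Figure D3:**
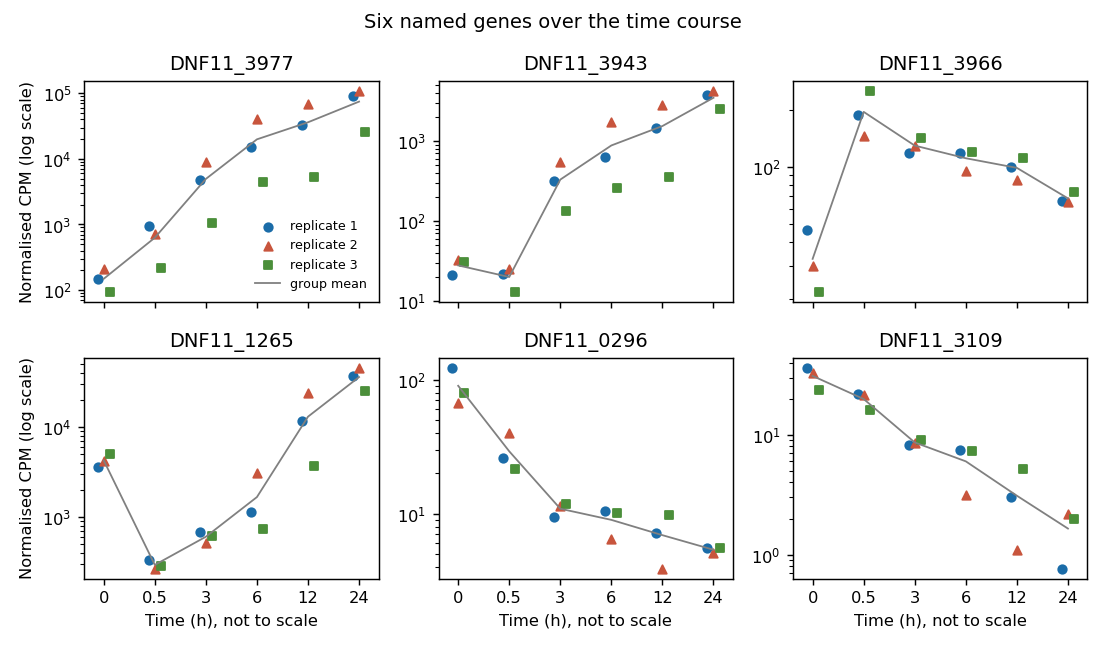
Normalised level of 6 named genes (CPM on the TMM scale, log axis) by time in sodium propionate in hours, with a point per library, its shape and colour giving the replicate number, and a grey line through the means of 3 libraries. DNF11_3977 and DNF11_3943 rose to means of 74700 and 3456 CPM at 24 h, DNF11_3966 was highest at 0.5 h, DNF11_1265 fell to 292.0 CPM at 0.5 h before it rose, and DNF11_0296 and DNF11_3109 fell to 5.37 and 1.65 CPM.

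Neighbouring times resembled each other more than the first and last did. Across genes, which are not independent replicates, the log2 fold changes against control had a correlation of 0.56 between 0.5 and 3 h, 0.94 between 3 and 6 h, 0.92 between 6 and 12 h, 0.92 between 12 and 24 h, and 0.16 between 0.5 and 24 h. All of these comparisons share the control libraries, and groups simulated without any change gave correlations of 0.48 to 0.50. The covariance exceeded the simulated one by 0.22 between 0.5 and 3 h, 0.62 between 3 and 6 h, 0.76 between 6 and 12 h, 1.26 between 12 and 24 h and 0.08 between 0.5 and 24 h. Between 12 and 24 h, 836 genes were higher at both times and 776 lower at both on the TMM scale. Independent lists of those sizes would share 279 and 284. By total count 269 genes were higher at 12 h and 229 at 24 h, so no more than 229 could be higher at both. The simulated groups, which hold no changed genes, shared 0 calls in each pair of times, so that value sets only the level without any effect. Between 0.5 and 24 h, 173 were higher and 99 lower at both times on the TMM scale, where independent lists would share 86.5 and 65.9. The 3 control libraries are too few to be split, so part of the excess of these overlaps over independent lists may come from the shared controls.

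The libraries were also placed on the line between the control mean (position 0) and the 24 h mean (position 1). Mean positions were 0.01 ± 0.04 in the control, 0.07 ± 0.02 at 0.5 h, 0.35 ± 0.07 at 3 h, 0.46 ± 0.18 at 6 h, 0.66 ± 0.29 at 12 h and 0.98 ± 0.15 at 24 h (SD, n = 3 each). The 3 h, 6 h and 12 h libraries overlapped, with ranges of 0.27 to 0.42, 0.31 to 0.65 and 0.37 to 0.94, so the groups were not separated on this line. Within each of the 3 replicate numbers, which were not treated as pairs, the position was higher at 6 h than at 3 h and higher at 12 h than at 6 h. Each 3 h, 6 h and 12 h library lay above each control and 0.5 h library.

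**Figure D4:**
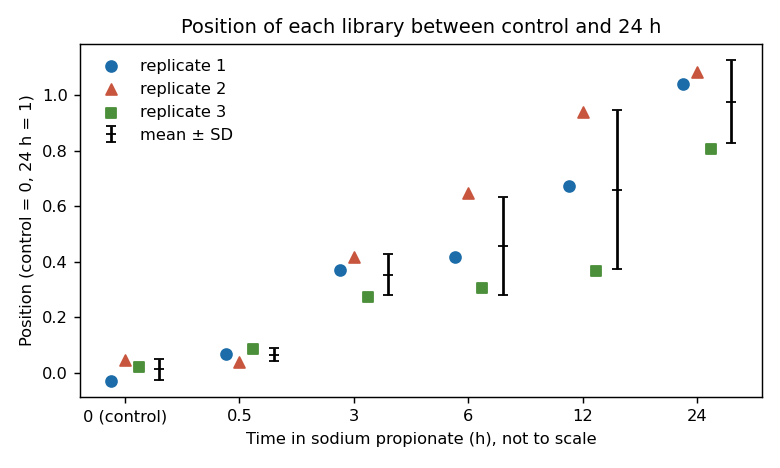
Position of each library between the control mean (0) and the 24 h mean (1) on the vertical axis, without unit, by time in sodium propionate in hours, with a point per library, its shape and colour giving the replicate number, and black bars giving mean ± SD of 3 libraries. The 12 h libraries lay at 0.67, 0.94 and 0.37, and the 24 h libraries at 1.04, 1.08 and 0.81.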

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

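The test of gene length and the count of opposite calls under other scales were chosen after the results were seen. The test of the 10 most abundant genes and the splits were chosen before. For leaving out 100 or 200 genes, no prediction was written in advance.

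Between 24 h and 0.5 h, 2544 genes differed in the direct edgeR contrast on the TMM scale. Of the 360 genes called against the control at both times, 88 were called in opposite directions. All 88 passed the direct contrast, which their selection nearly ensures. They were 35 genes that were higher at 0.5 h and lower at 24 h, and 53 that were lower and then higher; independent lists of those sizes would hold more, 155 opposite calls. With DESeq2 size factors, 29 of the 35 and 52 of the 53 had opposite calls again. With scaling by total count, 0 of the 35 did, although all 35 had opposite signs, and 12 of the 53 did, with 19 of the 53 opposite in sign. That scale moves the 24 h changes down together, with a median of -2.06 against -0.10 with TMM, so the loss of opposite signs among the 53 follows from the scale.

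Most genes fell in CPM at 24 h, with a mean over the 3 libraries of the median log2 change against control of -2.11 ± 0.35 (SD) by total count. CPM already divides by the total count, which at 24 h was 91.4% of that in the control. Depth was not tested further for this median, since the fit on libraries thinned to 1 total count bears on the called genes only. The tables argue against a loss that depends on coding length as a main cause. The rank correlation of the 24 h change with coding length across genes was -0.0639 (95% bootstrap interval -0.09 to -0.03). RNA fragmentation that acts alike on genes of all lengths would leave no such trend, so this test cannot decide on RNA quality. In 3 equal classes by length, the median TMM log2 fold change at 24 h was 0.02 (shortest), -0.24 (middle) and -0.13 (longest). These differences do not run one way with length and are small beside the fall of -2.11. The 10 most abundant genes are not the whole cause, because the median was still -1.72 ± 0.27 without them, but it was -1.04 ± 0.18 without the 100 most abundant genes, which held 67.2% of counts at 24 h and 30.3% in the control. Without the 200 most abundant genes it was still -0.88 ± 0.15, so these genes do not account for the whole fall either. What stays open is whether most transcripts declined in number or a wider set of genes rose, since the counts are relative. Propionate and time in culture, the biological differences of this design, cannot be separated.

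Other splits of the libraries were tried for each count of called genes. For 0.5 h the real value was 493 and the highest of the other splits gave 7; for 3, 6, 12 and 24 h and for 24 h against 0.5 h the real values were 1247, 1340, 1810, 2548 and 2544 and the highest other gave 0. In each of these, 1 of the 10 splits of the 6 libraries, the real one, gave as many, and 10 splits are too few for a share under 0.05. For change at any time, the real grouping, with 2888 genes, was the only 1 of 100 to give as many and the highest other gave 1055. A share under 0.05 argues against chance as the source of that count. The regroupings took the libraries as exchangeable, although same-numbered libraries of the later groups were correlated.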

How the results depend on the processing

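The alternatives chosen after the data had been seen were the fit without replicate 2 at 6 h and replicate 3 at 12 h and the fit on thinned libraries. Over all alternatives, 384 of 384 values of named genes in the comparisons that named them kept their direction and their side of the threshold. These genes were chosen as the largest changes in the same data, so their selection nearly ensures this. It does not cover other comparisons, where DNF11_3966 at 24 h changed sign by total count. Among the counts of called genes, 110 of 123 stayed within 1.5 times. The counts that moved further were those at 0.5 h (493), 3 h (1247), 6 h (1340) and 12 h (1810). Scaling by total count gave 205, 629 and 758 at 0.5, 3 and 6 h. DESeq2 gave 748 at 0.5 h. A fit of only the 6 libraries compared gave 1060, 2017 and 1161 at 0.5, 3 and 12 h. Leaving out replicate 2 at 6 h and replicate 3 at 12 h gave 862 at 0.5 h. Neither library belongs to the groups of that comparison, so they act on its count only through what the joint fit shares. With only the 6 libraries compared, the count at 12 h (1161) was below that at 3 h (2017). The rise of the count from 3 to 12 h therefore depends on the joint fit. The 24 h count stayed within 1.5 times of its main value with only the 6 libraries compared. The joint fit shares 1 estimate of spread, whereas the SD of position was 0.02 at 0.5 h, 0.07 at 3 h and 0.29 at 12 h. Whether this unequal spread is the cause was not tested. With each library left out in turn, the counts ran from 277 to 553 at 0.5 h, 876 to 1046 at 3 h, 1001 to 1314 at 6 h, 1389 to 2311 at 12 h, 2214 to 2509 at 24 h, 2218 to 2475 for 24 h against 0.5 h and 2490 to 3335 for any time. The 4 libraries that moved the 0.5 h count by more than 1.5 times were control replicate 1 (315), control replicate 3 (277) and replicates 1 (308) and 3 (299) at 0.5 h. The stricter filter gave the same 7 counts as the main filter, so it tests nothing. The replicate numbers were not treated as pairs, because in none of the comparisons made did all 3 same-numbered pairs correlate above 0.1 in their deviations from the group means. Among the later groups, all 3 did between 6 and 12 h (0.49 to 0.90), 12 and 24 h (0.39 to 0.62) and 6 and 24 h (0.25 to 0.46). These groups were not contrasted with each other in edgeR, and their fold changes and positions were set side by side without pairing. Across the time course, 10 of 18 libraries correlated best with their own number. With the replicate number as a block, 753 genes were called at 0.5 h, and the other 6 counts stayed within 1.5 times. Gene list tests and their alternatives were not run, since no list could be matched. Depth limits genes of low abundance most at 24 h, where the median count was 296 against 1439 in the control.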

Other observations

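The tests of replicate order and of exchanged labels, and the shuffles of runs, were chosen after the results were seen; the test of spill from neighbours was not.

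At 0.5 h the change depended weakly on coding length. Across genes, the rank correlation between log2 fold change and coding length was -0.19 (95% bootstrap interval -0.22 to -0.16) at 0.5 h, and between -0.06 and -0.04 at the later times. The median log2 fold change at 0.5 h was 0.10 in the shortest, 0.02 in the middle and -0.08 in the longest of 3 equal classes of genes. At 24 h these medians were 0.02, -0.24 and -0.13, which differ but do not run one way with length. Genes are not independent replicates, and no explanation was tested for the trend at 0.5 h.

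Genes with adjacent locus tags changed together. Across 4082 pairs of adjacent tags, the rank correlation of log2 fold changes was 0.20 at 0.5 h, 0.23 at 3 h, 0.23 at 6 h, 0.28 at 12 h and 0.33 at 24 h, each with a permutation p of 1e-04 before and after adjustment over the 5 times, the smallest that 10000 permutations can give. At 24 h it was 0.15 for tags 2 apart, 0.05 for tags 3 apart and -0.0028 for tags 10 apart, and 40 runs of 6 or more adjacent tags were called in one direction, against a median of 5 and at most 15 in 1000 shuffles, although the longest run, of 12 tags, did not exceed the longest in the shuffles, also 12. Spill of reads from an abundant neighbour was predicted to leave a correlation near 0 in pairs of similar level. At 24 h it was 0.40 (95% bootstrap interval 0.36 to 0.45) in pairs whose mean levels differed by less than 2-fold. In pairs that differed by 8-fold or more it was 0.16, and at 0.5 h the 2 values were 0.21 and 0.17. The test cannot decide on spill, because mean levels were taken over all libraries, those at 24 h included. Pairs that changed alike were thereby sorted towards similar levels. It stays open whether neighbours share regulation, whether overlapping transcripts share reads or whether reads spilled. Gene coordinates and strand were not used here, no biological explanation was tested, and the order of tag numbers along the genome is assumed.

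The 12 h libraries lay far apart on the line from control to 24 h, at 0.67, 0.94 and 0.37, and replicate 3 at 12 h was nearest to replicate 3 at 6 h (rank correlation 0.995, against at most 0.939 with its own group), while replicate 2 at 6 h was nearest to replicate 1 at 12 h. A nearest library in another group was not particular to these libraries. The best rank correlations of replicates 1, 2 and 3 at 6 h were 0.992, 0.984 and 0.995 with another group. With their own group they were 0.976, 0.976 and 0.975. An exchange of the labels of replicate 2 at 6 h and replicate 3 at 12 h cannot be told apart from real spread, since the deviations left after a smooth fit on position resembled the library's own replicate number more than the other in 3 of 4 comparisons across genes. For replicate 3 at 12 h the correlations with its own and the other number were 0.46 and -0.62 at 3 h and 0.38 and 0.23 at 24 h, and for replicate 2 at 6 h they were 0.49 and -0.68 at 3 h but -0.43 and 0.0045 at 24 h. Cultures of one replicate number may have moved at their own pace, since replicate 2 was ahead of 1 and 1 ahead of 3 at 3, 6, 12 and 24 h, but the order at 0.5 h was 3, 1, 2 and the exact permutation p of a shared order over the 5 times was 0.182. Both stay open, because the comparisons with the replicate numbers run both ways and the shared order rests on the times from 3 h onwards.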
